A study of Mus musculus with 2 samples.

How the data were processed

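Lung mesenchymal cells of wild-type C57BL/6 mice at postnatal day 8 were sorted by the authors as cells negative for Epcam, CD45 and CD31, per the labels, and 18000 cells went into each of 2 single-cell ATAC-seq libraries. The labels give the same batch for both libraries and say that lungs of males and females were taken, without saying which animals went into which library. The files used here are, for each library, a list of peak intervals and a list of cell barcodes. The deposited peak lists hold intervals without a score, height or count, and a count per cell and peak was not used here. Cell Ranger ATAC 2.1, Cell Ranger, Seurat, Signac and the mouse build mm10 are named in the submitters' processing notes with no role or order. The peak calling settings are not given in the sources used here. Since only 240 intervals were identical between the lists, the deposited lists were treated as called separately per library. Peak positions are printed as the files give them. The sources used here do not say whether the first base is counted from 0 or 1, so a start may be off by 1 base, which is far below the peak width.

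Replicate 1 held 215267 peaks and replicate 2 held 212344, after 1 and 2 lines that were emptied for this work. Peaks on unplaced contigs were kept out of the comparisons, which left 215217 and 212297 peaks on chromosomes 1 to 19, X and Y. Peak width had a mean of 848.2 bp (SD over peaks 95.1) in replicate 1 and 850.4 bp (92.7) in replicate 2. Doublets, barcodes that hold more than 1 cell, were not removed here, since the files used give no values per cell, and whether the authors removed them is not given in the sources used here. The number of reads behind a peak is unknown, so the peaks could not be weighted by depth, and a region without a peak may have been open in too few cells to be called. The number of shared barcodes, 183, corresponds to a pool of 685109 barcodes if both lists were drawn at random from it.

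Gene positions came from NCBI RefSeq's gene table of GRCm38.p6, the assembly also called mm10, which gave 49943 gene records on these chromosomes, 21887 of them protein-coding. That table gives outermost gene coordinates and no strand, transcript start, exon or sequence. The planned transcription start sites were therefore replaced by either end of the gene record, and the planned split into exons and introns by gene end, gene body and intergenic. The planned matching of random lists on promoter CpG ratio was replaced by gene length, and the planned motif enrichment, with RUNX motifs near gene lists, was not analysed here. These replacements were made after the files had been seen.

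Peaks were called shared when they overlapped by at least 1 bp, and the chance level came from 100 random placements of the other list within each chromosome. Peaks within 1 kb of a gene end, from the peak's nearest edge, were gene-end peaks for the location shares, with 20 random placements as the chance level. A gene had a gene-end peak when a peak lay within 500 bp of either end. Distal peaks of a gene had their midpoint in the gene or within 10 kb of it and lay more than 1 kb from the end of any gene record. Since 1 peak can lie in the region of several genes, it can be counted more than once.

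Before the data were examined, 21 gene lists with 334 distinct genes were fixed, and all genes had a gene record. They cover lung mesenchyme transcription factors, alveolar myofibroblast, alveolar fibroblast and lipofibroblast, adventitial fibroblast, smooth muscle, pericyte, mesothelium, extracellular matrix, the TGF-beta, Hedgehog, PDGF and Hippo pathways, and housekeeping genes. Epithelium, endothelium and immune lists stand for the cells that the sort removes. The lists of glia and neural crest, hepatocyte, skeletal muscle, neuron and germ cell stand for other cells. Each list's share or mean was ranked among 10000 random lists of protein-coding genes with the same number of genes per length decile. Percentiles above 97.5 or below 2.5 in the mean of both replicates are reported as high or low. A single gene was ranked among the 200 protein-coding genes nearest to it in length. With 1 group and 2 replicates no test between conditions was possible and no p-value was computed, and means are given with the SD over 2 replicates.

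The genes named were set before the data were examined: Runx1, Runx2, Runx3, Cbfb, Pdgfra, Acta2, Tbx4, Foxf1, Tcf21, Epcam, Ptprc and Pecam1, the 10 protein-coding genes with the most distal peaks, the 2 members of each list with the most distal peaks, up to 2 members of each list without a gene-end peak, and the 5 widest shared peaks. Genes named outside that rule are marked as chosen after their values were seen. Alternatives covered the overlap required, the peak width, the window at gene ends, the flank, the assignment of peaks to the gene of the nearest end, the matching of random lists and each replicate left out.

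The procedures were tested on simulated data. Of replicate 1 peaks copied and shifted, 100% were found again, and 0.0186% of the peaks left out of the copy overlapped it by chance. For distal peaks over 21887 genes, 4.5% of 200 simulated unchanged lists of 15 genes passed the 97.5th percentile, and 31% of lists with a 1.5-fold and 65% of lists with a 2-fold change did, so a list that did not pass may still differ. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1, and figures matplotlib 3.10.9. Intervals for shares of peaks are Wilson intervals at 95% and that for barcodes is exact, and they cover counting error only.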

Results

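Chromatin accessibility was measured by single-cell ATAC-seq in mesenchymal cells of the mouse lung on postnatal day 8, the period in which alveoli form. In this assay the Tn5 transposase cuts open chromatin in nuclei that each carry a DNA barcode, and clusters of cuts are called as peaks. The cells came from wild-type C57BL/6 mice and lacked Epcam, CD45 and CD31, the surface markers of epithelium, blood cells and endothelium. Both libraries belonged to 1 group with 2 replicates and 18000 cells entered each library, so the design held no contrast between conditions and replicate was compared with replicate. Replicate 1 had 215217 peaks on the main chromosomes and 11800 cell barcodes, and replicate 2 had 212297 peaks and 10625 barcodes. The barcodes amounted to 65.6% and 59.0% of the input cells. Nothing in the labels said whether the replicates came from separate animals, so the spread between them may be technical in part, although their sex chromosomes differed by more than the autosomes. Gene-end peaks at 4 Y-linked genes in replicate 1 alone and at Xist in replicate 2 alone argue against the same mix of animals in both. Sex may therefore be mixed with replicate in the spreads and the single-replicate peaks given below.

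Most accessible regions were found in both libraries. Of the replicate 1 peaks, 87.1% shared at least 1 bp with a replicate 2 peak, against 13.3% for replicate 2 peaks placed at random on the same chromosomes. Of the replicate 2 peaks, 88.3% shared at least 1 bp with replicate 1, against 13.4% at random. The mean of the 2 directions was 87.7%. Both directions come from 1 comparison of the lists, so this mean has no spread over replicates. Merged together, the lists held 239666 regions, of which 187224 (78.1%) had a peak in both replicates. Across protein-coding genes, the log2 number of distal peaks correlated between replicates with a Pearson r of 0.975, where genes are not independent replicates. The median peak width was 878 bp in replicate 1 and 879 bp in replicate 2, and the peaks covered 182.5 Mb and 180.5 Mb. Only 240 intervals were identical between the lists, and 183 barcodes occurred in both, 1.72% of those in replicate 2 (exact 95% interval 1.48 to 1.99).

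Peaks were concentrated in genes and at their ends. A gene end here was either outermost coordinate of a gene record, since the gene table gave no strand. A gene-end peak therefore need not lie at a promoter. Within 1 kb of a gene end lay 16.0% ± 0.0945 of the peaks (SD, n = 2), 1.87 times the 8.54% of random placements. Gene bodies away from the ends held 51.5% ± 0.487 (SD, n = 2), 1.20 times the 43.0% at random, and intergenic sequence held 32.5% ± 0.581 (SD, n = 2), 0.670 times the 48.5% at random. Of 21887 protein-coding genes, 70.1% in replicate 1 and 69.7% in replicate 2 had a peak within 500 bp of an end. Such a peak was present in both replicates at 14986 genes and in neither at 6285 genes, and 4417 genes (20.2%) had no peak in the gene or within 500 bp of it in either replicate. With protein-coding gene ends alone, the share of peaks within 1 kb of a gene end was 9.97%.

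Gene lists fixed in advance were used to ask which cell programmes had accessible gene ends. Gene-end peaks were present at all 14 smooth muscle genes, all 15 pericyte genes, all 12 Hippo pathway genes, all 11 Hedgehog pathway genes and all 8 genes of glia and neural crest in both replicates. In the extracellular matrix list, which holds collagens, elastin and the proteins that assemble them, 30 of 31 genes had one in both replicates, a share of 96.8% against 79.6% in random lists of like gene length. The alveolar myofibroblast list, genes of the contractile cells that lay down elastin at the tips of growing septa, had 20 of 21 (95.2% against 79.4%). Among lung mesenchyme transcription factors 32 of 37 had a gene-end peak in both replicates (mean share 91.9% against 77.5%), among adventitial fibroblast genes 14 of 15 (96.7% against 75.0%) and among TGF-beta pathway genes 18 of 19 (97.4% against 80.3%). Hepatocyte genes stood at the other extreme. Only 35.7% of them had a gene-end peak in each replicate, against 72.8% at random, and Apoc3, a plasma lipoprotein gene, had no peak in the gene.

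Each list was ranked among 10000 random lists of protein-coding genes matched on gene length, as a description without a p-value. Smooth muscle (98.8), pericyte (98.9), Hippo pathway (98.5), extracellular matrix (99.7), transcription factors (99.1), adventitial fibroblast (98.8), TGF-beta pathway (98.5), housekeeping genes (98.6) and alveolar myofibroblast (97.7) lay above the 97.5th percentile, 9 of 21 lists. The hepatocyte list (0.155) lay below the 2.5th, and chance gives 0.525 lists per tail. Between these limits were Hedgehog pathway (96.5), glia and neural crest (96.6), alveolar fibroblast and lipofibroblast (93.1), germ cell (83.4), endothelium (76.2), mesothelium (75.7), skeletal muscle (53.5), PDGF pathway (50.6), epithelium (42.4), neuron (38.9) and immune (8.02). The Hedgehog pathway and glia lists had a gene-end peak at every gene in both replicates, so no higher percentile was possible for them. In replicate 1 alone 5 of the 9 high lists passed, without transcription factors, alveolar myofibroblast, adventitial fibroblast and TGF-beta pathway, and in replicate 2 alone 8 passed, without alveolar myofibroblast. With a peak required over the gene end itself 5 passed, without transcription factors (84.3), adventitial fibroblast, TGF-beta pathway and Hippo pathway, and the immune (0.275) and epithelium (1.72) lists joined hepatocyte below the 2.5th percentile. With peaks of at least 800 bp 4 passed, without alveolar myofibroblast (71.0), adventitial fibroblast, TGF-beta pathway (70.2), Hippo pathway (84.2) and housekeeping genes, and alveolar myofibroblast was also lost with peaks of at least 500 bp (95.3). With a peak counted anywhere in the gene 6 passed, 3 of the 9 (extracellular matrix, transcription factors and housekeeping genes) with epithelium (99.5), endothelium (99.4) and germ cell (98.8), and no list was low.

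**Figure D1:**
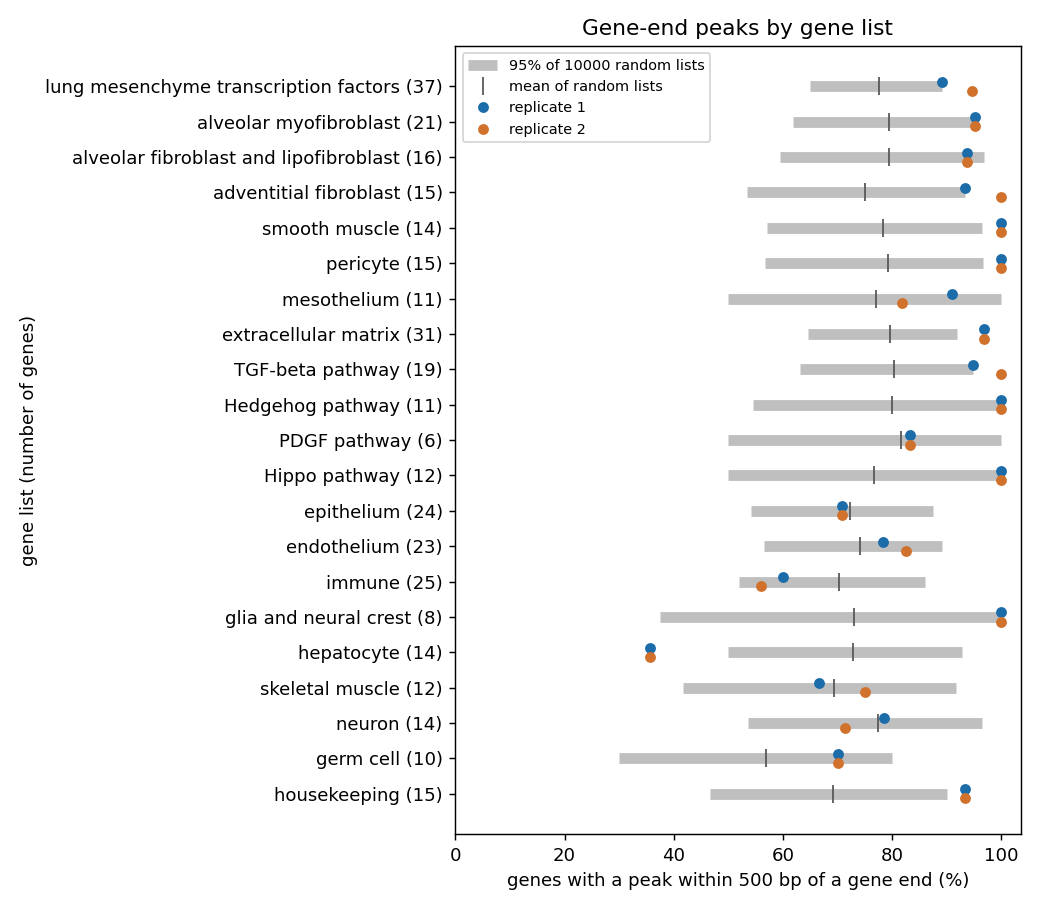
Share of genes in each list with a peak within 500 bp of a gene end, in percent (x axis), for replicate 1 (blue) and replicate 2 (orange); grey bars span the central 95% of 10000 random lists of like gene length and the tick marks their mean. The smooth muscle and pericyte lists sit at 100% in both replicates, and the hepatocyte list at 35.7% lies left of its bar.

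Distal peaks, those more than 1 kb from every gene end and inside the gene or within 10 kb of it, were counted for the same lists. The lung mesenchyme transcription factors carried 25.0 ± 0.382 distal peaks per gene (SD, n = 2), 2.03 times the 12.3 of random lists of like length. TGF-beta pathway genes carried 19.4 ± 0.186 (1.97 times), alveolar myofibroblast genes 19.1 ± 0.640 (1.91 times), Hedgehog pathway genes 18.9 ± 0.514 (1.79 times) and extracellular matrix genes 14.3 ± 0.228 (1.46 times; SD, n = 2). In both replicates, more distal peaks than the mean of genes of like length were counted at 33 of 37 transcription factors, 17 of 19 TGF-beta pathway genes, 19 of 21 alveolar myofibroblast genes, 10 of 11 Hedgehog pathway genes and 27 of 31 extracellular matrix genes. These 5 lists lay at percentiles of 100, 99.9, 99.8, 98.0 and 97.7, and none of the 21 lists lay below the 2.5th percentile. Counts above the like-length mean were also common in lists that did not pass. They were seen at 13 of 15 pericyte, 13 of 15 adventitial fibroblast, 12 of 14 smooth muscle and 10 of 12 Hippo pathway genes. In the lists of removed cells they were seen at 16 of 23 endothelium, 16 of 24 epithelium and 6 of 25 immune genes. With peaks of at least 800 bp the extracellular matrix list no longer passed (95.8). Some genes belong to more than 1 list, so the lists are not independent.

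The other fibroblast, smooth muscle and pericyte lists and the Hippo pathway lay between the 90th and the 97.5th percentile. Adventitial fibroblast genes had 9.17 ± 0.141 distal peaks per gene (percentile 97.3), smooth muscle genes 15.8 ± 0.556 (96.4), alveolar fibroblast and lipofibroblast genes 17.2 ± 0.133 (93.8), Hippo pathway genes 13.1 ± 0.118 (93.7) and pericyte genes 14.5 ± 0.471 (90.4; SD, n = 2). Mesothelium, the cell layer on the lung surface, had 3.73 ± 0.129 (4.93), and the 6 PDGF pathway genes had 11.6 ± 0.354 (52.7). Lists of the removed cells lay at 8.85 ± 0.154 for endothelium (73.5), 4.50 ± 0.412 for epithelium (56.1) and 2.60 ± 0.509 for immune genes (9.11). Lists of other tissues lay at 8.82 ± 0.455 for neuron (67.9), 2.42 ± 0.354 for skeletal muscle (33.6), 2.40 ± 0.141 for germ cell (71.3) and 2.50 ± 0.101 for hepatocyte (8.45). The remaining lists lay at 6.38 ± 0.354 for glia and neural crest (73.6) and 2.97 ± 0.330 for housekeeping genes (87.4). With a flank of 50 kb, or with 50 in place of 10 length bins, 10 lists lay above the 97.5th percentile, among them germ cell (99.9) with the wider flank and glia and neural crest (97.9) with 50 bins.

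**Figure D2:**
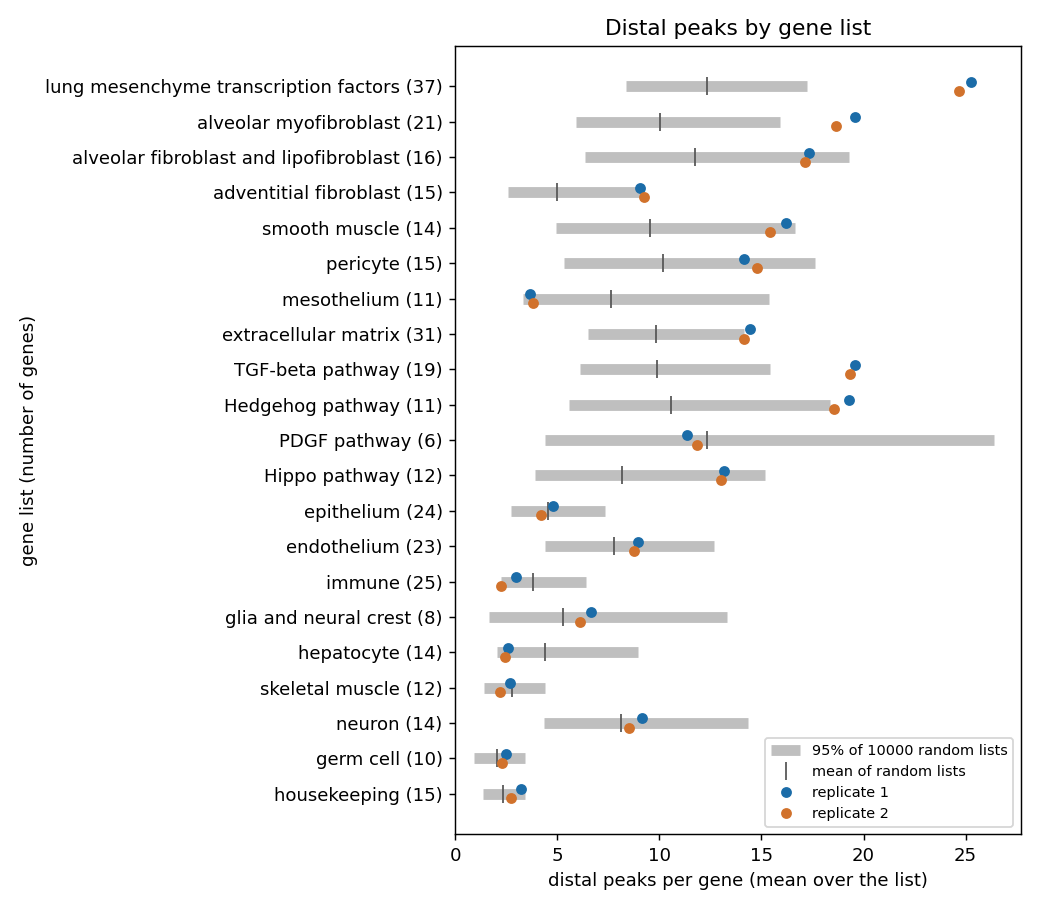
Mean number of distal peaks per gene in each list (x axis) for replicate 1 (blue) and replicate 2 (orange); grey bars span the central 95% of 10000 random lists of like gene length and the tick marks their mean. The transcription factor, alveolar myofibroblast, TGF-beta pathway, Hedgehog pathway and extracellular matrix lists lie to the right of their bars as means of both replicates.

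Runx1, the transcription factor in the title of the study, had a dense set of accessible regions. Its gene record (NCBI gene 12394, chromosome 16, 92601466 to 92826074, GRCm38) held 53 distal peaks in each replicate with its flanks, against a mean of 26.8 in genes of like length (percentile 91.8). With each peak given to the gene of its nearest end at any distance, Runx1 had 127.5 (mean of both replicates). A peak lay at the lower-coordinate end of the record in both replicates (92601072 to 92601914 in replicate 1), and no peak lay within 500 bp of the upper end. Without strand, it is not known here whether that peak lies where the gene starts or where it stops. A promoter inside the record would be counted among the distal peaks unless it lay near another gene's end. Runx2, a related factor of bone formation, had 45 and 44 distal peaks (percentile 64.3), Runx3 13 and 10 (80.0) and Cbfb, the shared partner of the Runx proteins, 6 and 5 (48.0). Runx1, Runx2 and Cbfb had gene-end peaks in both replicates, and Runx3 had a gene-end peak in replicate 2 alone.

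**Figure D3:**
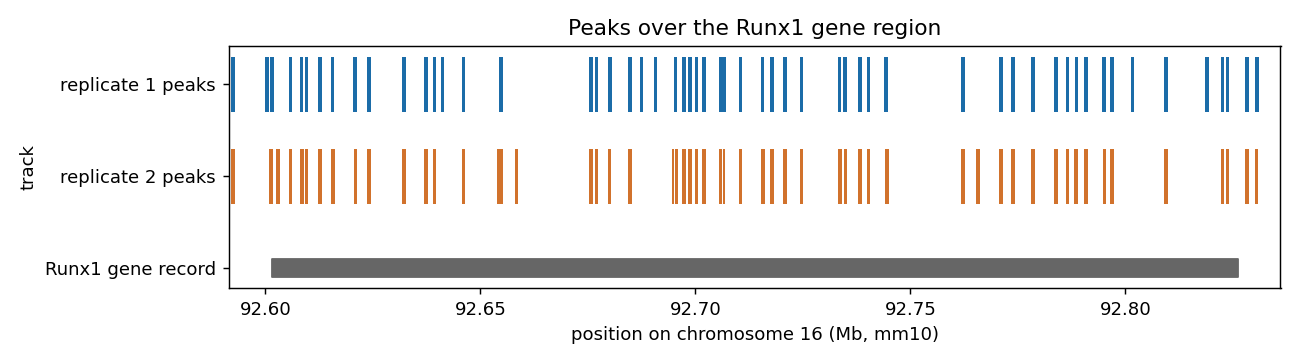
Peaks over the Runx1 gene record and 10 kb on each side, by position on chromosome 16 in Mb (x axis), for replicate 1 (blue) and replicate 2 (orange), with the gene record in grey. Each bar is a peak drawn to scale, and both replicates had 53 distal peaks in this region.

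Several genes of the mesenchyme and PDGF pathway lists had more distal peaks than nearly all genes of like length. Pdgfrb, the PDGF receptor of pericytes, had 15 and 17 against a mean of 5.11 (percentile 100). Pdgfa, a ligand of the PDGF receptors that was listed for the pathway and for no cell type, had 12 and 13 against 2.78 (percentile 100). Acta2, the smooth muscle actin of contractile cells, had 10 and 8 against 2.83 (99.3), Tbx4, a T-box factor of lung mesenchyme, 12 and 13 against 4.36 (99.3) and Foxf1, a forkhead factor of the same cells, 6 and 4 against 1.34 (98.3). Pdgfra, the receptor that marks fibroblasts and myofibroblasts, had 10 in each replicate against 6.09 (81.5). All of these genes except Pdgfa had gene-end peaks in both replicates, and Tcf21, a factor of lipofibroblasts, had a gene-end peak in both but no distal peak within 10 kb in either. With a flank of 50 kb Tcf21 had 11.0 (mean of both replicates), and with each peak given to the gene of its nearest end it had 23.5, Foxf1 40.5 and Pdgfra 25.5.

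Among the members with the most distal peaks of their lists, Tgfbr3, a co-receptor of TGF-beta, had 56 and 52 against 21.5 in genes of like length (percentile 100). Synpo2, an actin-binding protein of smooth muscle, had 48 and 51 against 19.2 (99.5), Fbn1, the main protein of microfibrils, 61 and 59 against 25.9 (98.5) and Col4a2, a basement membrane collagen, 39 in each replicate against 17.2 (98.0). Wwtr1, which encodes the Hippo effector TAZ, had 33 and 32 against 15.8 (97.5). Foxp1 had 132 and 121 against 48.3 (96.5) and Nfia 108 and 106 against 48.9 (93.0), and for such long genes the reference spans a wide range of lengths. Among other long genes, Egfem1 94 and 86 (81.5), Ltbp1 68 and 72 (83.8), Limch1 62 in each (88.8), Mylk 56 and 45 (83.8), Ebf1 55 and 63 (70.0), Gli2 45 in each (82.0) and Gli3 46 and 44 (69.3). Tead1 had 47 and 50 (87.3), Col14a1 41 and 44 (80.0), Col15a1 26 and 22 (87.0), Macf1 51 and 46 (68.8), Lama4 25 and 28 (73.0), Pdgfc 15 and 16 (38.0) and Cdh4 64 and 51 (67.3). In the mesothelium list Wt1 had 7 and 9 (69.3) and Upk1b 7 and 8 (87.8).

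Members of the mesenchyme, matrix and PDGF pathway lists without a gene-end peak were few. Nfia, Nebl, Inmt, Loxl2, Pdgfa and Muc16 had none in either replicate, nor did Ywhaz in the housekeeping list. Of these, Inmt and Muc16, a mucin of the mesothelium, had no peak in the gene at all, and Muc16 and Loxl2, a collagen cross-linking enzyme, had no distal peak where genes of like length had 21.6 and 11.2. Nfia, Pdgfa and Ywhaz each had more distal peaks than like-length genes, and since the outermost coordinates of all gene models were used, a missing gene-end peak does not show a closed promoter. Since either end counted, a gene-end peak does not show an open promoter.

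Genes of the cells that the sort removed kept some accessible regions. Epcam, the marker used to remove epithelium, had a gene-end peak in both replicates and 2 and 1 distal peaks against 2.89 in genes of like length (percentile 26.8). Pecam1, which encodes CD31, had no gene-end peak but 13 and 17 distal peaks against 7.59 (88.5), and Ptprc, which encodes CD45, had no gene-end peak and 11 and 8 against 14.7 (31.5). With each peak given to the gene of its nearest end, Ptprc had 60.0 (mean of both replicates). The members with the most distal peaks were Etv5 (13 and 11) and Cdh1 (12 and 10) for epithelium, Erg (44 and 42) and Flt1 (32 and 24) for endothelium, and Ptprc and Itgb2 (10 and 8) for immune cells. Ager, Cldn18, Egfl7, Emcn, Cd3e and Cd79a had no gene-end peak, and Cd3e, a chain of the T cell receptor complex, had no distal peak and no peak in the gene. Since the files used here hold peak intervals without counts, the share of cells behind a peak is unknown.

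In the lists of other cells and of housekeeping genes the leading members lay on both sides of the mean of their length class. Cps1 (12 in each replicate, percentile 42.3) and Hnf4a (10 and 9, 57.5) led the hepatocyte list, Syt1 (38 and 39, 47.5) and Rbfox3 (39 and 36, 46.8) the neuron list, and Ddx4 (6 and 5, 47.8) the germ cell list. Tnnt3 (6 in each, 91.8), Nobox (4 in each, 91.5), Mbp (26 and 25, 89.0) and Foxd3 (6 and 5, 98.5) stood higher, Polr2a had 6 in each (87.0), Ywhaz 12 and 11 (97.8) and Pax7 7 and 4 (21.3). Gad2, Neurod2, Myh2, Myh4 and Tnp1 had no gene-end peak in either replicate, like Cps1, Hnf4a and Ddx4.

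The protein-coding genes with the most distal peaks were all long. Rbms3, which encodes an RNA-binding protein, had 190 and 186 over a record of 1057168 bp, and Arhgap26 had 174 and 172, Auts2 144 and 149, Rad51b 144 and 141, and Lrmda 137 and 143. Rora, a nuclear receptor, had 141 and 138, Wwox 132 and 137, Tenm4 137 and 122, Pde4d 130 and 128, and Sox5 136 and 122. All of these 10 except Pde4d had a gene-end peak in both replicates. Their rank among genes of like length is not given, since they were picked by number and the longest genes share nearly the same reference. The 5 widest replicate 1 peaks that overlapped replicate 2 were 1791, 1679, 1631, 1392 and 1327 bp wide. They lay 3376 bp from Cnrip1 on chromosome 11, in the predicted gene Gm39913 on chromosome 2, in Slc12a8 on chromosome 16, 4551 bp from Gm31579 on chromosome 6 and in Birc6 on chromosome 17. At the peaks near Cnrip1, in Slc12a8 and in Birc6, replicate 2 had 2 narrower peaks over the same sequence.

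Peaks of a single replicate were narrower and lay less often at gene ends. Replicate 1 had 27667 peaks (12.9%) with no overlap in replicate 2, with a median width of 833 bp against 882 bp for shared peaks, and 10.5% of them lay within 1 kb of a gene end against 16.9% of shared peaks. Replicate 2 had 24785 such peaks (11.7%), with medians of 850 bp and 881 bp and gene-end shares of 8.80% and 16.8%. Near immune genes 28 of 130 replicate 1 peaks (21.5%, Wilson 95% interval 15.3 to 29.4) and 7 of 109 replicate 2 peaks (6.42%, 3.15 to 12.7) were absent from the other replicate. Near epithelium genes the shares were 16.9% (12.0 to 23.2) and 7.14% (4.03 to 12.3), near endothelium genes 12.1% (8.66 to 16.7) and 8.91% (5.96 to 13.1), and near alveolar myofibroblast genes 17.4% (14.2 to 21.1) and 13.7% (10.8 to 17.2). Of the 42 list intervals, 4 left out the share over all peaks, where chance gives 2.1: immune and alveolar myofibroblast above it in replicate 1, and Hedgehog pathway (7.08%, 4.47 to 11.0) and glia and neural crest (4.17%, 1.43 to 11.5) below it in replicate 2. Against the share over all protein-coding gene regions, 13.3% in replicate 1 and 10.8% in replicate 2, 4 intervals also lay off: immune and alveolar myofibroblast above it and extracellular matrix below it in replicate 1, and pericyte above it in replicate 2. The intervals cover counting error only.

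The sex chromosomes differed between the replicates more than any autosome. On the 19 autosomes replicate 2 had 0.967 to 0.995 times the peaks of replicate 1 (mean 0.985, SD over chromosomes 0.00751), while on chromosome X it had 5021 against 4725 (1.06 times) and on chromosome Y 18 against 31 (0.581 times). The single-copy Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, which lie between 897566 and 1286628 on chromosome Y, each had a gene-end peak in replicate 1 and none in replicate 2. Xist, the X-linked RNA gene that acts in X inactivation in female cells, had a gene-end peak in replicate 2 and none in replicate 1, with 3 peaks and 1 peak in the gene. These genes were chosen after the chromosome numbers were seen. Gm52481, a predicted gene at 90742729 to 90745083 on chromosome Y, had a gene-end peak in both replicates. Beyond 90 Mb on chromosome Y lay 22 of the 31 peaks of replicate 1 and 17 of the 18 of replicate 2. In or within 10 kb of the 4 single-copy genes lay 4 peaks in replicate 1 and 0 in replicate 2. All 18 replicate 2 peaks on chromosome Y overlapped a replicate 1 peak.

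**Figure D4:**
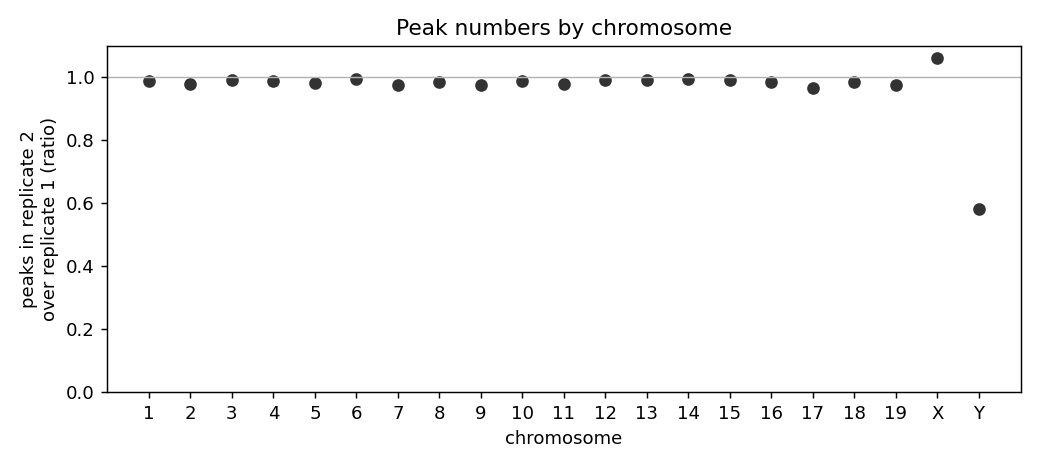
Number of peaks in replicate 2 divided by that in replicate 1 (y axis) for each chromosome (x axis), with a line at a ratio of 1; each point is 1 chromosome. The 19 autosomes lie between 0.967 and 0.995, chromosome X at 1.06 and chromosome Y at 0.581.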

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

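Peaks on unplaced contigs lay outside the comparisons and were above the 3 that a count of 0 allows. Replicate 1 had 50 and replicate 2 had 47 of them, of which 33 and 30 lay on the contig JH584304.1.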

How the results depend on the processing

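The alternatives with peaks of at least 800 bp, autosomes only, 50 length bins and a peak anywhere in the gene were chosen after seeing the data. With peaks of at least 800 bp, 86.5% of peaks were shared against 87.7%, and 16.1% of peaks lay near a gene end against 16.0%. That share was 12.5% within 500 bp and 9.97% with protein-coding gene ends only, both narrower by construction. Of gene lists high at gene ends there were 9, against 5 with a peak over the end itself, 4 with peaks of at least 800 bp, 5 to 8 with a replicate left out and 6 with a peak anywhere in the gene, which kept 3 of the 9 and added epithelium, endothelium and germ cell. With random lists not matched there were 12, since alveolar fibroblast and lipofibroblast, Hedgehog pathway, and glia and neural crest were added to the 9. The 1 low list became 3 over the end itself (epithelium and immune added), 2 with peaks of at least 800 bp (immune added) and 0 with a peak anywhere in the gene. Of lists high for distal peaks there were 5, against 10 with a flank of 50 kb, 10 with 50 length bins and 8 with random lists not matched, each including the 5, and 4 with peaks of at least 800 bp, where extracellular matrix was lost (95.8). The added lists were adventitial fibroblast, smooth muscle and Hippo pathway with both of the former, pericyte and germ cell with the flank, alveolar fibroblast and glia with the bins, and alveolar fibroblast, smooth muscle and pericyte without matching. Adventitial fibroblast was also added with peaks of at least 500 bp (97.5) and in replicate 2 alone (97.7). Low lists numbered 0, against 1 with a flank of 50 kb (mesothelium) and 1 without matching (immune). Reciprocal overlap of 50%, peaks of at least 500 bp and the gene of the nearest end kept the numbers of shared or single-replicate peaks and of lists, where they applied, within 1.5 times, though germ cell was added with the nearest end. Where a value moved, the cause was not tested unless stated. Over single lists, 18 distal percentiles newly passed a limit, 1 no longer did and 149 kept their side, and 9, 22 and 137 did so at gene ends, with no list going to the tail opposite to its reported one, though epithelium, not called, lay at 1.72 with a peak over the end itself and at 99.5 with a peak anywhere in the gene. Of distal counts of named genes under 3 alternatives, 157 moved by more than the replicate SD and 83 did not. Of 80 genes, 40 rose by over 1.5 times with the 50 kb flank, which is wider by construction, and with the nearest end 24 rose and 6 fell by as much (Foxf1 5.00 to 40.5, Ptprc 9.50 to 60.0, Arhgap26 173 to 55.5). Other motif windows and backgrounds, and other RUNX motif windows and flanks, were set in advance and not run, for want of sequence here. The number of reads per peak is unknown, so depth could not be varied.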

Other observations

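In this part, the tests of depth, of Y-linked genes, of transcription factor families, of the share of immune families needed and of chance among list intervals were chosen after the results they bear on were seen, as were the gene families, windows and single genes named. Receptor genes of the nose were nearly free of peaks. Of 1106 olfactory receptor genes, 3.16% in replicate 1 and 3.44% in replicate 2 had a gene-end peak, against 24.1% of random genes of like length, and of 353 vomeronasal receptor genes 1.13% and 1.42% did, against 41.8%. Beta-defensins, antimicrobial peptides of epithelia, had 11.9% and 16.7% against 59.7%. Ribosomal protein genes lay at 90.9% and 92.2% against 58.8%. Forkhead genes had 9.64 and 9.23 distal peaks per gene, 2.05 times the value at random, and Sox genes 12.2 and 11.3, 2.52 times. Single long genes weigh on both means. Sox5 alone had 136 and 122 distal peaks among 19 Sox genes, and Foxp1 132 and 121 among 44 Forkhead genes. The means without them were not computed, so these values do not show a trait of the whole family. T-box genes, at 1.17 times (percentile 74.3), and collagens, at 1.08 times (72.8) with gene-end peaks at 84.1% against 82.9%, did not stand apart as families. The 13 T-box genes differed among themselves. Tbx2, Tbx3, Tbx4 and Tbx5, all in the transcription factor list, lay at percentiles of 99.5, 100, 99.3 and 99.3 among genes of like length, and Tbx18 at 48.8. Zinc finger genes named Zfp had gene-end peaks at 83.1% and 81.7% against 76.5% but only 0.764 times the distal peaks.

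Peaks were counted in fixed windows of 100 kb, and windows at other positions were not tried. The fixed window with the most peaks lay in Nfib, a nuclear factor I gene that acts in lung maturation. It had 38 and 37 peaks between 82400001 and 82500000 on chromosome 4. It was followed by a window in Tns1 on chromosome 1 with 36 and 37 and by a window over Thra and Nr1d1 on chromosome 11 with 36 in each replicate. Among pericyte genes, Kcnj8 had 8 distal peaks in each replicate against 1.67 in genes of like length and Gucy1b1 16 in each against 5.68. Smad3, a TGF-beta signal transducer, had 36 and 37 against 14.4, and Smad7, its inhibitor, 18 in each against 4.08. Sftpc, the surfactant gene of alveolar type 2 epithelium, had a gene-end peak and 6 distal peaks in both replicates against 1.37, although epithelium was removed. Its record lies between those of Bmp1 and Lgi3, and when each peak went to the gene of its nearest end, Sftpc had 0, Bmp1 7 and 8, and Lgi3 3 in each replicate.

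More X-linked and fewer Y-linked peaks were called in replicate 2 than in replicate 1. A difference in depth or peak calling that acted alike on all chromosomes would not put the X ratio, 1.06, above the highest autosome at 0.995. That ratio is the observation that raised the question, so it is no separate test. A few odd X regions are argued against by 28 of 29 bins of 5 Mb (96.6%) that had a higher ratio than the median autosomal bin. A larger share of female cells in replicate 2 may account for the pattern, as a hypothesis: 4 of 4 single-copy Y-linked genes had a gene-end peak in replicate 1 and none in replicate 2, and Xist had one in replicate 2 alone. A prediction written beforehand, that overlapping X peaks would be wider in replicate 2, did not hold. The difference was -1.71 bp (SE 0.830), in the opposite direction and below every autosome (-1.39 to 1.59). Peaks gained or lost outright are not in such pairs. Whether peak width follows the share of female cells was not tested. The labels name both sexes and no library, so the sex of each library was not tested against a record. If the libraries differed in sex, sex and replicate cannot be told apart in any difference between them.

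The transcription factor, alveolar myofibroblast and extracellular matrix lists had more distal peaks than genes of like length. Incomplete matching of gene length is argued against by the 3 of 3 lists that passed with 50 length bins. For peaks counted for overlapping neighbouring genes, each peak was given only to the gene of its nearest end, and the same 3 of 3 passed. That count has no limit of distance, so it also depends on how far the neighbouring genes lie, which was not matched. It therefore cannot decide whether peaks counted more than once add to the excess within 10 kb. For the transcription factor list, regulatory genes of any tissue may carry more distal peaks. Outside the lists, 139 genes of families such as Fox, Sox, Pax and Gata had 1.40 times the value of genes of like length (percentile 99.8). Sox5, with 136 and 122 distal peaks, was among these genes and weighs on that value. Zfp and T-box genes were not among the families used. They had 0.764 and 1.17 times the value at random, so the excess was not shared by all families of transcription factors. The T-box value includes Tbx2, Tbx3, Tbx4 and Tbx5 of the list itself, so it does not describe T-box genes outside the list. Random lists were then drawn by length from 176 transcription factors. These were the 139 outside the lists and the list's own 37, so the list was compared partly with itself. It had 1.15 to 1.40 times the value at random. Its percentiles were 99.6, 94.2, 97.9 and 98.5 with 4, 8, 12 and 16 length bins. The limit of 97.5 was passed with 4, 12 and 16 bins and not with 8. This explanation therefore cannot be told apart from one specific to mesenchyme, as the outcome changed with the bins. No explanation specific to mesenchyme was tested for this pattern, since the design has 1 group.

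Near immune genes, replicate 1 had more peaks of its own. More carried-over immune cells in replicate 1 were looked for at 268 genes outside the lists. These genes were picked by symbol from families such as Cd, Clec, Tlr and Klr. Their difference in peaks per gene lay at percentile 57.5, below the 90 set beforehand as counting against such carry-over. A symbol does not show that a gene is particular to immune cells, so this value cannot decide the question. The families would have passed the 97.5th percentile had 20.7% of them carried the excess of the immune list. An excess at fewer genes would therefore have been missed. The immune list's own share also stays open. It lay above the share over all peaks in replicate 1. In replicate 2 it lay below that share, with an interval that held it (6.42% against 11.7%). The immune list's own difference, 0.840 peaks per gene, lay at percentile 99.3, on the list that raised the question, with epithelium at 97.0 and pericyte, at -0.800, at 2.17. Chance among the intervals of all lists was also looked at. Of 42 intervals, 4 left out the share over all peaks where chance gives 2.1, and 1 of the 4 was of alveolar myofibroblast, cells that the sort keeps. That count ignores how far an interval lies off and takes the lists as independent, though some share genes. It therefore cannot decide whether chance accounts for the immune share.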
